A study of Mus musculus with 4 samples.

How the data were processed

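The arrays measured RNA from Kupffer cells, the resident macrophages of the liver, and SL4 cells, a mouse colon carcinoma line. Per the labels' protocols, the Kupffer cells were sorted from 12-week-old female C57BL/6 mice that were wild type or lacked Clec4n, the gene for the fungal-pattern receptor Dectin-2. In each group 100000 Kupffer cells and 100000 SL4 cells were kept for 8 hours, either together or apart. Where they were kept apart, the RNA of both cultures was mixed before the array, per the series' design text, so that every array holds RNA of both cell types. cDNA was made from 20 ng of total RNA with a whole-transcriptome amplification kit, labelled with biotin and hybridised to 1-colour arrays, per the labels' protocols.

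The deposited values are probe set intensities on a linear scale, 1 per probe set and array. They were made with Affymetrix Expression Console 1.4 and the MAS5 algorithm, per the submitters' processing notes. MAS5 subtracts a local background and scales each array to a common trimmed mean. The values bear this out, since the mean after trimming 2% of each tail was 497 or 498 in all 4 arrays. Because of that scaling the values are relative within an array, and a change in the total RNA per cell cannot be seen. No detection calls were used here.

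The table held 45037 probe sets. The platform annotation gave 1 gene symbol to 34945 of them and several to 932, and 9160 were not listed in it and are unnamed here. Symbols were looked up through Entrez numbers in a RefSeq gene table of assembly GRCm38.p6, which held 34741 of the 34945 and changed 0 symbols. That table was used for names only. The named probe sets covered 18193 genes, of which 9010 had more than 1 probe set. A gene's value was that of its probe set with the highest mean log2 signal over the 4 arrays.

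Signals were raised to a floor and then log2-transformed, with no further scaling. The plan, fixed before the data were examined, took the floor from odorant and vomeronasal receptor probe sets if at least 100 were named, and otherwise from the median of all probe sets over the 4 arrays. Only 80 were named, so the floor was the median, a signal of 76.1. A comparison covered the genes above the floor in at least 1 of its arrays. Where the dimmer array lay at or under the floor, the ratio is a lower bound and is written as "at least". No ratio is given where both arrays lay at or under it.

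Each group had 1 array. No test was made and no p-value is given, and the number of arrays limits the precision. An additive fit of culture and genotype over the 4 arrays, with 1 residual degree of freedom, was not made. Genes were counted where the ratio was at least 2-fold, and for the difference of differences where the ratios of the genotypes differed at least 2-fold. There were 5 comparisons: co-culture over separate culture in each genotype, knockout over wild type in each culture condition, and the difference between the co-culture changes of the genotypes. In that difference, a genotype with both arrays at or under the floor entered with a ratio of 1. The 2 co-culture comparisons share no array, nor do the 2 genotype comparisons, so each pair was set side by side by correlation across genes and by the overlap of the 2-fold lists beside the overlap of independent lists. Genes are not independent replicates, so these correlations are descriptions. As a repeat within the arrays, the second probe set of a gene was set against its brightest one.

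Genes are named by a rule fixed before the data were examined. For each comparison it took the 10 highest and 10 lowest ratios among genes measured above the floor in all arrays of the comparison, and for the 4 pairwise comparisons up to 5 of the largest lower bounds per direction. A named gene had 1 symbol that is not provisional, a brighter array of at least 2 times the floor, and probe sets that all pointed in the same direction. Members of the fixed gene lists and Clec4n may also be named.

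The 36 gene lists, also fixed beforehand, covered the cell types that the cultures held or could hold and the pathways the design brings to mind. Of their 686 entries, 56 matched no gene of the array. A list with at least 5 genes in a comparison was described by its median log2 ratio and by the percentile of that median among 10000 random lists of the same size, matched on signal in 10 bins. A percentile under 2.5 or over the matching upper limit is called standing apart. This describes these arrays and is not a test of the conditions.

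The calculations were checked on simulated arrays built from the mean log2 signals of the 4 arrays, with 200 of 10527 genes changed by known factors. Their noise was taken from the knockout over wild-type differences, so the number of unchanged genes called follows from those differences. For the wild-type co-culture comparison, 4% of genes changed 1.5-fold, 98% of those changed 2.5-fold and 100% of those changed 4-fold or 8-fold were called 2-fold, and 23 unchanged genes were called. With no change simulated in the knockout comparison, 30 of 10496 genes were called. The changed genes were drawn only from those over 4 times the floor in every array, so the shares recovered do not cover dimmer genes. Of the 129 genes called 2-fold in the measured wild-type co-culture comparison, 54 had a brighter array at 2 to 4 times the floor. Of 200 lists without a shift, 3 stood apart.

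The alternatives were quantile normalization, centring the arrays on a common median, no floor with 16 added to each signal, the median over a gene's probe sets, list medians relative to the pan-macrophage list, and list members held by 1 list only. The planned floor alternative, the median of all probe sets, had become the floor itself. The receptor-based floor of 22.9 and a limit of 4 times the floor on the brighter array were added after the data were seen. So were the tolerances for calling a value moved, namely the SD of the ratios between the separate-culture arrays for single genes, the SD of random lists for list medians and a step of 0.1 for correlations. RNA quality and hybridisation controls had been planned, but the control probe sets were not used here. Coordinates were not used here. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.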

Results

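Expression was measured in 4 groups of mixed cells: wild-type Kupffer cells with SL4 cells in separate culture, Dectin-2 knockout Kupffer cells with SL4 cells in separate culture, and the same pairs in co-culture. Each group had 1 array, so no group has replicates and no difference was tested. The culture comparison was made once in each genotype and the genotype comparison once in each culture condition. The median signal was 72.5 in the wild-type separate array, 75.8 in the knockout separate array, 78.4 in the wild-type co-culture array and 77.5 in the knockout co-culture array. Between 10117 and 10187 genes per array lay above the floor of 76.1, and 9727 did so in all 4 arrays. Floored log2 signals correlated across all probe sets with Pearson's r between 0.992 and 0.995 for the 6 pairs of arrays. Without the floor r was between 0.947 and 0.952.

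Clec4n, which encodes Dectin-2 and was deleted in the knockout cells, was near background in every array. Its brighter probe set read 14.2 in the wild-type separate array and 17.6 in the wild-type co-culture array, against 8.29 and 8.19 in the knockout separate and co-culture arrays. Its second probe set read 4.21 and 7.35 in wild type and 0.629 and 3.49 in knockout. All of these values lay under the floor, so no fold is given, although wild type was the brighter genotype in both conditions. Whether the probe sets lie in the deleted part of the gene is not known, so this is a weak check of the labels.

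The cell type lists lay at different signal levels, which for different probe sets do not measure the share of each cell type. Cell cycle genes were bright, with a median signal of 4052 over the 4 arrays, and housekeeping genes had a median of 8631. Genes of mesenchymal cells and matrix were also bright in part, with Sparc, a matrix glycoprotein, between 7090 and 8387, and Col3a1, a fibrillar collagen, between 2191 and 3206. The 22 epithelial and colon carcinoma markers had a median of only 18.3, and Spint1, an inhibitor of membrane proteases, was the brightest of them at 667 to 869. Most genes of the sorted macrophages were dim: the 23 pan-macrophage and leukocyte markers had a median of 40.2 and the 18 Kupffer cell identity genes of 47.9, both under the floor. Among macrophage genes, Lyz2, which encodes lysozyme, read 88.2 to 138, Cd68, a late endosomal glycoprotein, 92.2 to 175, and C1qb, a complement component, 100.3 to 264. Brighter members were Id3, a transcriptional regulator, at 1960 to 2232, Cd53, a leukocyte tetraspanin, at 615 to 793 and Laptm5, a lysosomal protein of leukocytes, at 350 to 502. Genes of leukocytes that were not put in culture were dimmer still, with medians of 11.5 for neutrophil, 11.7 for T and NK cell and 13.9 for B cell markers, against 3.29 for the receptor genes of smell.

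**Figure D1:**
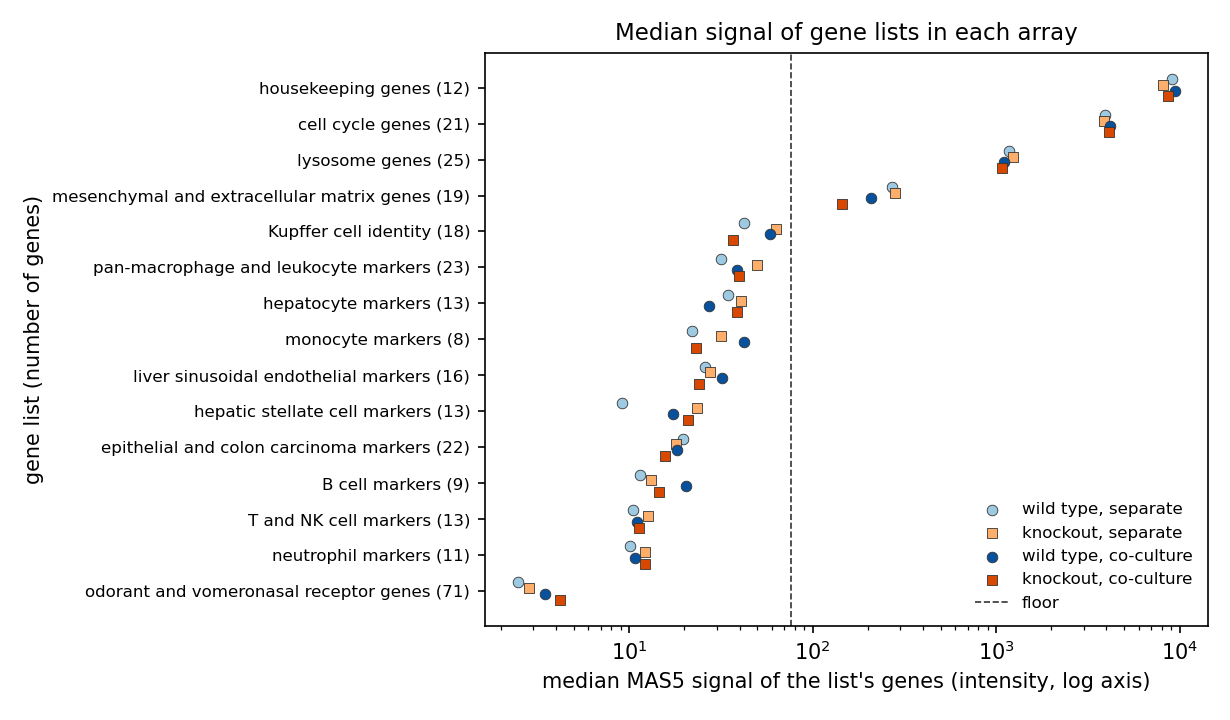
Median MAS5 signal of the genes of each list in each array, on a log axis, with 1 point per array and the floor as a dashed line. Numbers in brackets are the genes per list. Cell cycle genes lie near 4052, the macrophage and Kupffer cell lists at 40.2 and 47.9 over the 4 arrays, under the floor of 76.1, and the receptor genes at 3.29.

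The question of the design was what co-culture with tumour cells does to gene expression and how much of it depends on Dectin-2. With wild-type Kupffer cells, co-culture had far higher Cxcl1, a chemokine that attracts neutrophils, at a signal of 12375 against 321 in separate culture, 38.5-fold. Ptgs2, the inducible enzyme of prostaglandin synthesis, was 7.65-fold higher, and Ccl2, a chemokine that attracts monocytes, at least 6.13-fold higher. Cav1, the main coat protein of caveolae, was 3.84-fold lower, and Dkk2, a secreted modulator of Wnt signalling, 3.49-fold lower. Of 10417 genes above the floor, 73 were at least 2-fold higher in co-culture and 56 at least 2-fold lower.

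Among the other genes with the highest ratios in wild type, Igfbp7, a secreted protein that binds insulin-like growth factors, was 7.93-fold higher and Rrad, a Ras-related GTPase, 5.07-fold higher. Bcl3, an atypical member of the IkappaB family, was 4.54-fold higher, Selp, which encodes P-selectin, 4.47-fold and Cd82, a tetraspanin, 4.27-fold. Osbp2, an oxysterol-binding protein, was 4.14-fold higher, Rbm47, an RNA-binding protein, 3.89-fold and Nfkbiz, another atypical IkappaB protein, 3.83-fold. The growth factor gene Fgf7 was at least 4.73-fold higher, Tnfaip3, a negative regulator of NF-kappaB, at least 4.49-fold, Adm, which encodes adrenomedullin, at least 3.46-fold and Gap43, a protein of growing axons, at least 2.99-fold.

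Among the lower genes in wild type were 2 collagen genes, Col4a5 at 3.21-fold and Col7a1 at 2.69-fold. Ildr2 was 3.40-fold lower, Ptges3l 3.12-fold, Prss23, a serine protease, 3.08-fold and Smyd1, a methyltransferase of muscle cells, 2.97-fold. Sema5a, a guidance protein, was 2.64-fold lower and Emid1 2.61-fold. Nim1k was at least 3.16-fold lower, the transcription factor genes Mecom and Lbx1 at least 3.05-fold and 2.48-fold, Etl4 at least 2.43-fold and Kank1 at least 2.43-fold.

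Of the 23 lists that could be placed among random lists, 10 stood apart in the wild-type comparison, where 1.15 would by chance. Among NF-kappaB target genes 10 of 18 were at least 2-fold higher and 0 lower, the median log2 ratio was 1.04, and the percentile was 100. The higher ones included Ier3, a stress-response gene, at 3.78-fold, Nfkbia, the classical inhibitor of NF-kappaB, at 3.40-fold, Traf1, a signalling adaptor, at 3.17-fold, and Relb and Nfkb2, subunits of the factor itself, at 2.65-fold and 2.05-fold. Others were level or nearly so, such as Tnfaip2 at a log2 ratio of -0.10 and Plau, the urokinase gene, at -0.06. Of 29 chemokine genes, 6 lay above the floor in wild-type co-culture and only 4 in wild-type separate culture. The 6 had a median of 1.07, also at percentile 100, and 3 were at least 2-fold higher, namely Cxcl1, Ccl2 and Cxcl16 at 2.68-fold. Cxcl12, a chemokine of stromal cells, had a lower signal, 1295 against 2040.

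Of 29 cytokine genes, 11 lay above the floor in at least 1 wild-type array, with a median of 0.38 at percentile 99.9. Of the 11, 2 were at least 2-fold higher: Il11, a cytokine related to interleukin 6, at least 2.72-fold, and Tgfb1, transforming growth factor beta, 2.45-fold. Immediate early genes had a median of 0.18 at percentile 100, with Ier3 and Nr4a2, an orphan nuclear receptor, at 2.52-fold among the higher and Klf2, a transcription factor, 2.04-fold lower. Oxidative and metal stress genes had a median of 0.10 at percentile 99.9, led by Slc7a11, the cystine transporter, at 2.71-fold. Mesenchymal and matrix genes were lower, with a median of -0.45 at percentile 0 and 10 of 13 below 0, such as Col4a2 at -0.80 and Acta2, smooth muscle actin, at -0.73. The unfolded protein and amino acid stress list had a median of -0.12 at percentile 1.65, and Chac1, a glutathione-degrading enzyme, was 2.04-fold lower.

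Pan-macrophage markers moved with these lists in wild type, with a median of 0.41 over 9 genes at percentile 99.5, and so did alternative activation at 0.29 over 6 genes and killing and cell death effectors at 0.27 over 5. Relative to the pan-macrophage list the medians of cytokines, alternative activation and killing effectors were -0.04, -0.13 and -0.14, and without a floor those of cytokines, alternative activation, chemokines and pan-macrophage markers were 0.0047, 0.07, 0.41 and 0.24. Among genes with a brighter array of at least 4 times the floor, alternative activation was at 0.0052, killing effectors at 0.13 and chemokines at 1.66, and over members of 1 list only alternative activation was at 0.60 and chemokines at 1.42. C1qb was 2.63-fold higher and Csf1r, the receptor of macrophage growth factor, had a log2 ratio of -0.19. Of the 38 genes called 2-fold that had a second probe set above the floor, 26 moved the same way by at least 1.5-fold in it. Without a floor the counts were 351 higher and 228 lower, and as the median over probe sets Ildr2 had a log2 ratio of -0.80, Ptges3l of -0.57, Sema5a of -0.95, Lbx1 of -0.71, Col4a5 of -1.02 and Fgf7 of 1.498.

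With knockout Kupffer cells the co-culture had much the same leading genes. Cxcl1 was 31.8-fold higher, at 10366 against 326, Ptgs2 7.55-fold and Ccl2 at least 6.63-fold. Nfkbiz was 5.40-fold higher, Tnfaip3 4.42-fold and Igfbp7 4.32-fold. Cav1 was 4.65-fold lower and Col4a5 3.30-fold lower. Of 10444 genes above the floor, 70 were at least 2-fold higher and 60 at least 2-fold lower.

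Further genes with high ratios in knockout were Cd82 at 3.81-fold, Nfkbia at 3.62-fold, Traf1 at 3.47-fold and Selp at 3.43-fold. Bcl3 was at least 5.79-fold higher, Rrad at least 4.42-fold, Fgf7 at least 4.42-fold and Il11 at least 2.79-fold. Grtp1, a gene of a GTPase-activating protein, was 4.18-fold higher in knockout while its log2 ratio in wild type was -0.27. Lower genes were Nudt13 at 3.29-fold, Sycp3, a protein of meiotic chromosomes, at 2.99-fold, Pdlim2 at 2.96-fold, Smyd1 at 2.81-fold, Cplx2, a synaptic protein, at 2.80-fold, Sema5a at 2.61-fold, Dkk2 at 2.60-fold and Mylk4, a kinase of the myosin light chain kinase family, at 2.57-fold. Emid1 was at least 3.29-fold lower, S100a3 at least 2.65-fold, Tcea3 at least 2.64-fold, Sema3d at least 2.34-fold and Nudt18 at least 2.20-fold.

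In knockout, too, 10 of 23 lists stood apart, where 1.15 would by chance. NF-kappaB target genes had a median of 1.17 at percentile 100, with 10 of 18 at least 2-fold higher and 0 lower. Of 29 chemokine genes, 6 lay above the floor in knockout co-culture and only 4 in knockout separate culture. The 6 had a median of 1.02 at percentile 100, with Cx3cl1, a membrane-bound chemokine, at 2.09-fold among the 3 higher ones. Mesenchymal and matrix genes had a median of -0.40 at percentile 0, and Col5a2, a fibrillar collagen, was 2.36-fold lower. Immediate early genes were at 0.13, percentile 99.4, killing and cell death effectors at 0.34, percentile 99.8, and interferon-stimulated genes at 0.28, percentile 98.7, the last with 0 of 7 members at least 2-fold higher. Without a floor the medians of killing effectors, interferon-stimulated genes and chemokines were 0.12, 0.02 and 0.53, and among genes with a brighter array of at least 4 times the floor chemokines were at 1.897.

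Cholesterol synthesis genes were lower in knockout co-culture, with a median of -0.25 at percentile 0.07 and 15 of 17 below 0, such as Insig1, a sterol sensor, at -0.59 and Mvk, mevalonate kinase, at -0.54. Phagocytosis and efferocytosis genes had a median of -0.13 at percentile 2.11, and of -0.03 without a floor. Oxidative stress genes were at 0.15, percentile 98.6, and heat shock genes at 0.18, percentile 99.3, and with quantile normalization these medians were 0.06 and 0.06. Pan-macrophage markers had a median of 0.07 at percentile 82.4, and cytokine genes of 0.14 at percentile 96.5. Without a floor the cytokine median was -0.02, with the receptor-based floor it was -0.14, and among genes with a brighter array of at least 4 times the floor the pan-macrophage median was -0.26. Of the 37 genes called 2-fold with a second probe set above the floor, 26 moved the same way by at least 1.5-fold in it. Without a floor the counts were 300 higher and 214 lower, and as the median over probe sets Grtp1 had a log2 ratio of 1.24, Traf1 of 1.01, Col4a5 of -1.12 and Nudt13 of -1.11.

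The co-culture changes of the genotypes, which share no array, correlated across 10224 genes with Pearson's r = 0.53 and Spearman's rho = 0.41. There were 43 genes at least 2-fold higher in both, against 0.479 for independent lists of these sizes, and 23 at least 2-fold lower in both, against 0.323. No gene was 2-fold higher in one genotype and 2-fold lower in the other. Of the 72 genes higher in wild type and measured in both, 67 had a ratio above 1 in knockout, and of the 55 lower ones 50 had a ratio below 1. Without a floor r was 0.24 and 79 genes were higher in both, while 15 genes were lower in both with a common median and 14 with the median over probe sets. List members higher in both included Slc11a1, a metal transporter of phagosomes, at 2.51-fold in wild type and 2.32-fold in knockout, Cpt1a, the gate of fatty acid entry into mitochondria, at 2.33-fold and 2.82-fold, and Tgfb1 at 2.45-fold and 2.76-fold.

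**Figure D2:**
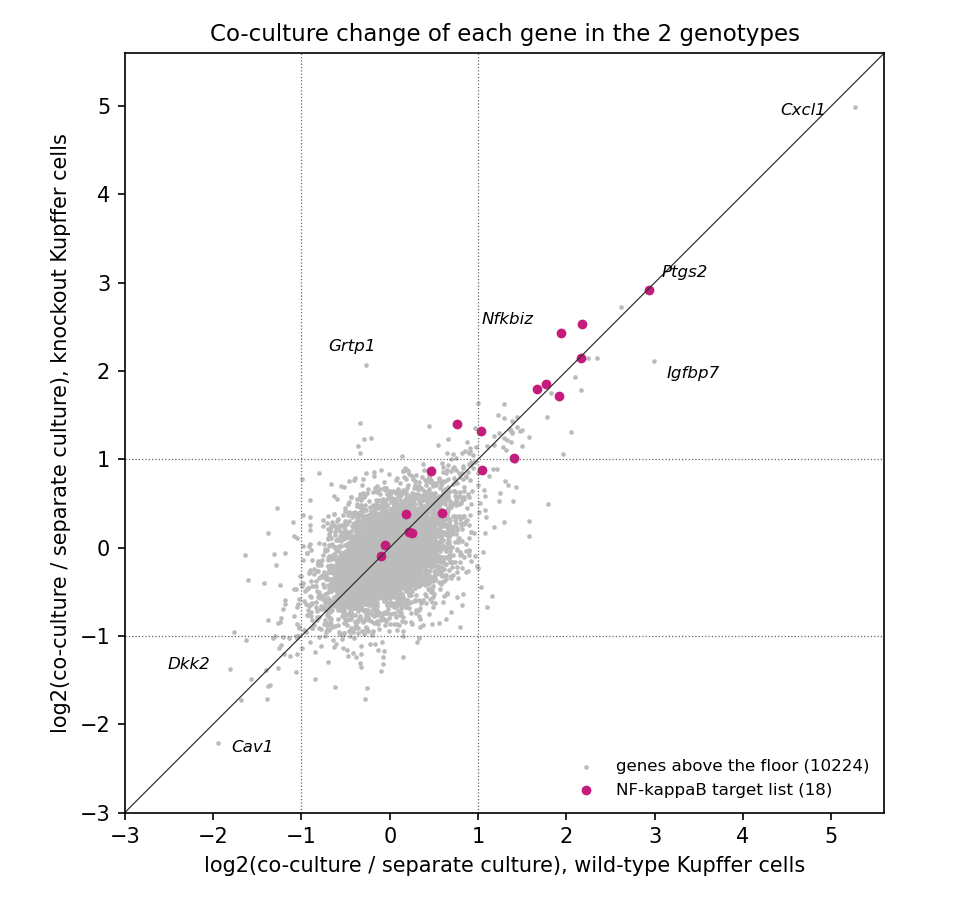
Log2 ratio of co-culture over separate culture for each gene above the floor, with wild-type Kupffer cells on the x axis and knockout Kupffer cells on the y axis. Grey points are 10224 genes, coloured points the 18 NF-kappaB target genes, dotted lines mark 2-fold and the diagonal marks equal ratios. Cxcl1 lies at 5.27 and 4.99, and Grtp1 lies off the diagonal at -0.27 and 2.06.

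**Figure D3:**
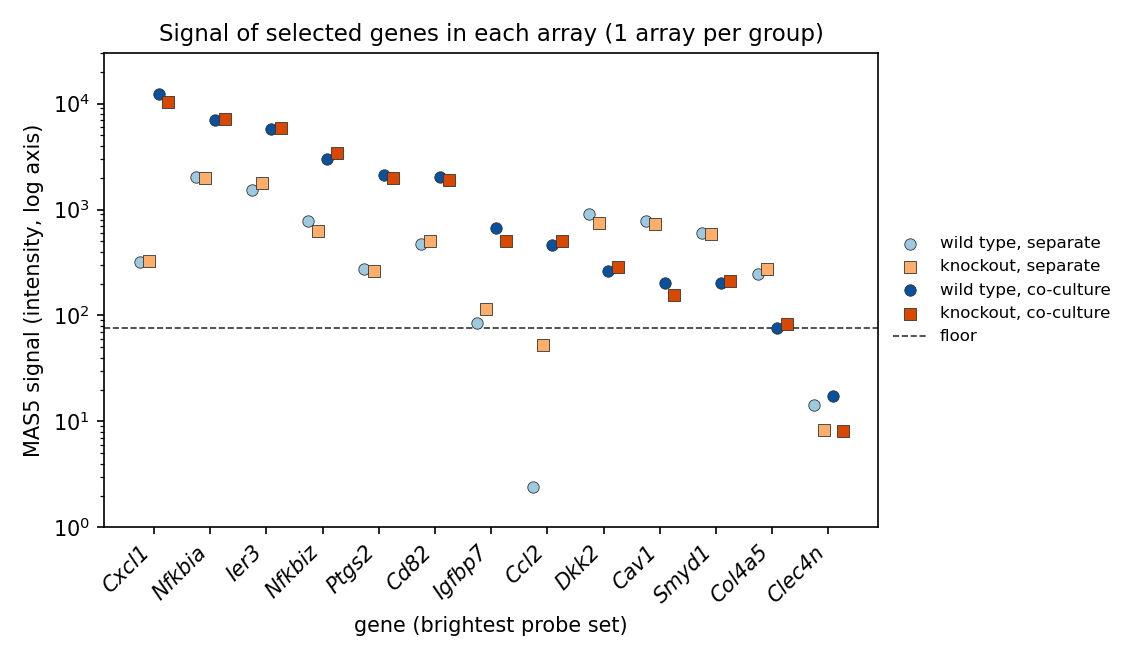
MAS5 signal of 13 named genes in each of the 4 arrays on a log axis, 1 point per array, with the floor as a dashed line. Cxcl1 reads 321 and 326 in separate culture and 12375 and 10366 in co-culture, Cav1 776 and 725 against 202 and 156, and Clec4n lies under the floor in every array.

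The genotype comparison within co-culture asked what differs when Dectin-2 is missing while both cell types are together. Few genes were called: of 10399 above the floor, 15 were at least 2-fold higher in knockout and 10 at least 2-fold lower. The 10399 include 1251 genes whose brighter array lay under 2 times the floor, Lyz2 among them, which could not reach 2-fold. Tmem259 was 3.19-fold higher in knockout, at 1008 against 316. H2-Aa, an MHC class II chain of antigen-presenting cells, was at least 2.15-fold lower, at 56.0 against 164 in wild type. Cxcl1 and Ptgs2 were close, at log2 ratios of -0.26 and -0.08.

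Other genes higher in knockout co-culture were Ston2 at 2.11-fold, Bbs1, a gene of the ciliary BBSome, at 2.10-fold, Bmf, a gene of cell death, at 2.09-fold, Rpusd3 at 2.08-fold, Hid1 at 2.03-fold, Cbx3, a heterochromatin protein, at 2.01-fold and Borcs5 at 2.01-fold, while Helz2 and Wdr78 were at 1.95-fold and 1.93-fold. Mecom was at least 2.44-fold higher, Mylk2 at least 2.41-fold, Tex52 at least 2.36-fold, Pde2a at least 2.31-fold and Lbx1 at least 2.11-fold. Lower in knockout were Gap43 at 2.36-fold, Ift172, a gene of ciliary transport, at 2.26-fold, Rhbdl1 at 2.15-fold and Sec22a at 2.01-fold. Klhl13 was just under 2-fold lower, Fam228b 1.93-fold, Zfp956 1.91-fold, Plpp1 1.90-fold, Gdpgp1 1.86-fold and Tsen34 1.84-fold, Mup3, a major urinary protein, at least 2.69-fold and Kcnh3 at least 2.05-fold.

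Of 23 lists, 0 stood apart in this comparison. NF-kappaB target genes had a median of 0.04 with 0 of 18 at least 2-fold apart, chemokines of -0.11 with 0 of 6, and the Dectin-2 signalling list, measured through genes such as Bcl10 and Malt1, of 0.00 with 0 of 8. Syk, the kinase of this pathway, lay under the floor in all 4 arrays. Of the 4 genes called 2-fold that had a second probe set above the floor, 0 moved the same way by at least 1.5-fold in it. Without a floor the counts were 214 and 170, among genes with a brighter array of at least 4 times the floor they were 2 and 1, and as the median over probe sets Ston2 had a log2 ratio of 0.56 and Kcnh3 of -0.66.

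In separate culture, the background for the genotype comparison, 9 genes were at least 2-fold higher in knockout and 12 at least 2-fold lower, of 10362. Of the 10362, the 1176 with a brighter array under 2 times the floor could not reach 2-fold. Prm1, a protamine of sperm, was 2.62-fold higher and Esr1, an oestrogen receptor, 2.10-fold higher. Grtp1 was 2.96-fold lower and Tubb3, a neuronal tubulin, 2.95-fold lower. Dusp10, a phosphatase of stress kinases, was 2.15-fold lower.

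Further genes higher in the knockout were Usp46os2 at 2.16-fold, Zfp850 at 2.03-fold, Ino80b at 2.01-fold, Rbm47 at 1.98-fold, Cpeb4 at 1.97-fold, Fam110a at 1.85-fold, Cep295 at 1.82-fold and Pcyox1l at 1.79-fold, with Egfl8 at least 2.27-fold and the ribosomal protein gene Rpl39 at least 2.09-fold higher. Lower were Ptges3l at 2.18-fold, Paqr8 at 2.16-fold, Vsig10 at 2.15-fold, Dmrt3 at 2.03-fold, Tigd3 at 2.01-fold, and Mup3 and Enho at 1.98-fold each, with Nim1k at least 3.16-fold and Kank1 at least 2.43-fold lower. Of 22 lists 1 stood apart, heat shock, with a median of -0.19 at percentile 0.98, such as Hspa8, a constitutive chaperone, at -0.33. With quantile normalization that median was -0.04, and the knockout separate array had the lowest 99th percentile of signal, 7637 against 8283 to 8433 in the others. Of the 9 genes called 2-fold with a second probe set above the floor, 0 moved the same way by at least 1.5-fold in it, and as the median over probe sets Esr1 had a log2 ratio of 0.55, Ptges3l of -0.55 and Dusp10 of -0.67. Without a floor the counts were 252 and 139.

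The genotype differences in co-culture and in separate culture correlated across 10124 genes with Pearson's r = 0.11 and Spearman's rho = 0.14. No gene was at least 2-fold higher in knockout in both conditions or at least 2-fold lower in both, where 0.0116 and 0.0098 would be for independent lists. There were 16 higher and 10 lower without a floor, 11 and 4 with the receptor-based floor, chosen after the data were seen, and 1 lower with quantile normalization or a common median. Mup3 came nearest, at least 2.69-fold lower in co-culture and 1.98-fold lower in separate culture.

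The difference of the co-culture changes asked which responses depend on Dectin-2. For 66 of 10637 genes the co-culture ratio was at least 2-fold larger in wild type than in knockout, and for 46 at least 2-fold smaller. Rhbdl1 had the largest excess in wild type, 3.41-fold, followed by Esr1 at 3.27-fold, Pcdhb14, a protocadherin, at 2.76-fold and Rps27, a ribosomal protein, at 2.71-fold. Grtp1 was the most reduced, its ratio being 5.05-fold smaller in wild type, followed by Tmem259 at 3.41-fold and Helz2, a helicase, at 3.36-fold. The 10 genes named above with the highest measured ratios in wild-type co-culture each differed by less than 2-fold, with log2 differences such as 0.02 for Ptgs2, 0.28 for Cxcl1, -0.49 for Nfkbiz, 0.74 for Osbp2, 0.88 for Igfbp7 and 0.90 for Rbm47.

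Others with a larger ratio in wild type were Nudt13 at 2.71-fold, Cpeb4, a regulator of translation, at 2.65-fold, Gtdc1 at 2.60-fold, Cxcr4, the receptor of Cxcl12, at 2.59-fold, Slc25a40 at 2.56-fold and Fbrsl1 at 2.49-fold. Others with a smaller ratio were Ptges3l at 2.94-fold, Paqr8 at 2.91-fold, Enho at 2.87-fold, Vsig10 at 2.71-fold, Ttll11 at 2.62-fold, Zfp523 at 2.61-fold and Ifi204, an interferon-inducible gene, at 2.38-fold. Ptpn6, a phosphatase of the Dectin-2 signalling list, had a co-culture ratio at least 2.32-fold smaller in wild type, and that of Adm was at least 2.46-fold larger, each with 1 array under the floor. The list of NF-kappaB target genes had a median difference of -0.05 at percentile 29.2, and 0 of 18 members differed 2-fold.

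Of 23 lists 1 stood apart in the difference, cholesterol synthesis, with a median of 0.16, above the upper limit, where 1.15 would by chance. The genotype differences in co-culture were shuffled among genes of like signal 1000 times. The number of genes at least 2-fold apart was then between 106 and 164 with a median of 133, and the observed number was 112. Every shuffle kept all the genotype differences, so this comparison cannot show whether any response depends on Dectin-2. Of 22 genes called 2-fold with a second probe set above the floor, 6 moved the same way by at least 1.5-fold in it. As the median over probe sets the log2 difference was 0.70 for Esr1, 0.78 for Nudt13, 0.88 for Cpeb4, 0.89 for Fbrsl1 and -0.83 for Ptges3l, all under 2-fold, and -1.62 for Grtp1, and without a floor the counts were 643 and 496.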

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

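All tests of explanations in this part were chosen only after the results were seen, and the rules that decide the 2 tests on macrophage and Kupffer cell markers and the test on Clec4n were reworded after their outcomes were known. Attention was drawn by genes whose co-culture change went in opposite directions in the genotypes, with 1 array per group, so that none of these differences was tested. The log2 change in wild type exceeded that in knockout by 1.770 for Rhbdl1, 1.709 for Esr1, 1.462 for Pcdhb14, 1.408 for Cpeb4, 1.381 for Gtdc1, 1.373 for Cxcr4, 1.355 for Slc25a40 and 1.317 for Fbrsl1, all higher in co-culture in wild type and lower in knockout. The opposite held, with differences of -2.335 for Grtp1, -1.768 for Tmem259, -1.748 for Helz2, -1.541 for Paqr8, -1.521 for Enho, -1.439 for Vsig10, -1.387 for Ttll11, -1.383 for Zfp523 and -1.249 for Ifi204. Among probe sets without a gene name, which the comparisons do not use, 2 were at least 2-fold higher in co-culture in both genotypes, where 0.190 would be for independent lists, and 2 were lower in both. There were 9160 such probe sets, 2934 of them above the floor in at least 1 array.

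NF-kappaB target genes were higher in co-culture in both genotypes. Scaling of the arrays as a cause is argued against by quantile normalization, which left the lower of the 2 list medians at 1.038, at percentile 100, and noise of single arrays by the 66 genes at least 2-fold higher in both genotypes or lower in both, where 0.802 would be for independent lists. The NF-kappaB list rose by more than the macrophage and Kupffer cell markers, its median exceeding the upper bound of theirs by at least 0.5969 on the log2 scale. This does not decide whether a larger share of Kupffer cell RNA was the whole cause. Most markers were dim, and the arrays do not show which cells gave their signal. The markers went apart, with Cd53 at 0.26 in wild type and -0.23 in knockout. C1qb was 2.63-fold higher in wild type, and Slc11a1 was at 1.33 and 1.21. The markers' median signals were 131 and 136. The pan-macrophage list stood apart in wild type at 0.41, while the Kupffer cell identity list stood apart in neither genotype, at 0.05 in wild type and 0.15 in knockout. Among genes with a brighter array of at least 4 times the floor, the identity medians were 0.69 in wild type and 0.70 in knockout. Few of the 7 identity genes above the floor are that bright. Slc11a1 is among them, so these medians do not add to its values and do not describe the list. The pan-macrophage median in wild type was 0.20 in that setting. A contribution of a larger share of Kupffer cell RNA thus stays open. That co-culture itself raises these genes stays a hypothesis, and the arrays do not show in which cell type.

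The macrophage and Kupffer cell lists had medians under the floor, although as many Kupffer cells as tumour cells were cultured and single members such as Id3, Cd53 and Laptm5 lay above it in every array. Low sensitivity of the arrays as a whole was examined with the cell cycle genes, whose lowest median was 3882 against the floor of 76.1. Each array is scaled to a common mean and the floor is the median of all probe sets. Strongly expressed genes therefore lie far above the floor in any case, and the test does not decide how well dim transcripts were detected. A small share of Kupffer cell RNA in every sample cannot be told apart from low expression of these genes after culture. The 41 macrophage and Kupffer cell genes had a median signal of 41.8 against 11.4 for 32 genes of other leukocytes, a log2 difference of 1.877 with a bootstrap interval of 1.26 to 2.81, but both medians lie under the floor and come from different probe sets. No biological explanation was tested.

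Differences of at least 2-fold between knockout and wild type were few, and with the floor used here 0 recurred in both culture conditions, against 16 higher and 10 lower genes with no floor. With the floor, genes whose brighter array lay under 2 times its value could not be called. If noise of single arrays made the 2-fold differences, a second probe set of the same gene would repeat few. It repeated 0 of 4 in co-culture and 0 of 9 in separate culture, which noise would give, but these are few genes. Over all genes with 2 probe sets, the higher of the 2 correlations between probe sets was 0.09637, against 0.491 and 0.484 in the co-culture comparisons. These correlations cover mostly genes not called 2-fold, so they do not decide whether the called differences were noise. A genotype effect hidden by a small share of Kupffer cell RNA cannot be told apart from no effect, because Clec4n itself reached only 17.58 in a wild-type array, under the floor. An effect of Dectin-2 in Kupffer cells thus stays open.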

How the results depend on the processing

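The receptor-based floor and the limit of 4 times the floor were chosen after the data were seen; the other alternatives were planned. The planned floor alternative, the median of all probe sets, is not a separate alternative here because it served as the floor. With 1 array per group no replicate could be left out in turn. A fit of culture with genotype as a block, over the 4 arrays, was not made.

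Pairs of counts below are genes at least 2-fold higher and lower. With no floor and 16 added to each signal, they were 351 and 228 for wild-type co-culture, 300 and 214 for knockout co-culture, 214 and 170 for knockout over wild type in co-culture, 252 and 139 in separate culture, and 643 and 496 for the difference of differences. The co-culture changes then shared 79 higher genes with r = 0.2413, and the genotype differences shared 16 higher and 10 lower. With the receptor-based floor the counts were 276 and 163 for wild-type co-culture, 230 and 199 for knockout co-culture, 135 and 120 for the genotypes in co-culture, 175 and 93 in separate culture, and 412 and 272 for the difference. The co-culture changes shared 81 higher and 35 lower genes with r = 0.3811, and the genotype differences 11 and 4. Both settings admit more dim genes.

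With a brighter array of at least 4 times the floor, the counts were 46 and 29 for wild-type co-culture, 31 lower for knockout co-culture, 2 and 1 for the genotypes in co-culture, 2 and 4 in separate culture, and 21 and 11 for the difference, and the co-culture changes shared 15 lower genes with r = 0.6516. This setting leaves fewer genes. Quantile normalization gave 5 genes higher in knockout in separate culture and 1 gene lower in knockout in both conditions, and so did centring on a common median for the latter, with 1 gene. Genes lower in co-culture in both genotypes numbered 15 with a common median and 14 with the median over probe sets. The cause was not tested for these.

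Relative to the pan-macrophage list, 3 list medians of the wild-type co-culture comparison reversed: cytokines at -0.03602, alternative activation at -0.1267 and killing and cell death effectors at -0.1425. This follows from subtracting that list's own median of 0.41. Otherwise 690 list medians moved by less than the spread of random lists and 154 by more. Of the values of named genes 670 moved little and 51 more, 32 of these with the median over probe sets. Part of the 670 could not move, so this count does not measure stability. The limit on the brighter array only selects genes and leaves each ratio as it was. The receptor-based floor leaves the ratios of genes above the main floor in all their arrays unchanged. The median over probe sets leaves genes with a single probe set unchanged. The NF-kappaB median stayed positive in both co-culture comparisons under every alternative run, from 0.63 to 1.07 in wild type and 0.91 to 1.36 in knockout. Between the genotype differences, r stayed between 0.05 and 0.17.

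Signal over background limits the precision. The SD of the log2 ratio between knockout and wild type in co-culture was 0.35 for genes at 2 to 4 times the floor and 0.13 at 16 times or more.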

Other observations

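Several further genes were lower in co-culture in both genotypes. They were chosen after their values were seen and form no list. Myl9, a myosin light chain, was 2.30-fold lower in each, and Mylk, the kinase of such chains, 2.05-fold in wild type and just over 2-fold in knockout. Cav2, the partner of Cav1 in caveolae, was 2.56-fold and 2.95-fold lower. Kitl, the ligand of the receptor KIT, was 2.35-fold and 2.15-fold lower, and Irs1, an adaptor of insulin signalling, 2.06-fold and 2.01-fold.

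Many inflammatory genes that macrophages are known to make were at or under the floor in all 4 arrays, among them Tnf, Il1b, Il10, Ccl3 and Ccl4. Csf1, a growth factor of macrophages, was bright throughout, at 3015 and 3104 in separate culture and 3914 and 3390 in co-culture. Vegfa, which drives vessel growth, read 806 and 798 against 1277 and 1372. Cell cycle genes were level, with co-culture medians of 0.04 in wild type and 0.06 in knockout over 21 genes.

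Xist, which is transcribed from the inactive X chromosome, was near background, at 12.2 and 23.2 in separate culture and 12.6 and 20.0 in co-culture, although the mice were female. Alb, the albumin gene of hepatocytes, read 324 to 347. Prf1, which encodes perforin of cytotoxic lymphocytes, read 816 to 943 while the median of T and NK cell markers was 11.7.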
